A study of Mus musculus with 26 samples.

How the data were processed

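The deposited log2 values were used as they stood. Per the submitters' processing notes, they came from RMA, whose version is not given, and Partek 6.6. The arrays were mouse Affymetrix HT MG-430 PM, and the labels name Trizol extraction, NuGEN Ovation Pico WTA V2 amplification and NuGEN Encore Biotin labelling. Of 45141 probe sets, 104 were controls; 29449 were in the annotation table, 28898 with 1 gene symbol and 551 with several, and 15692 had no gene. Entrez identifiers of 28689 probe sets were found in the gene table, which changed 0 symbols. For the 7180 genes with more than 1 probe set the brightest on average was taken, giving 17097 genes. Trp53, Atic, Cda and Ccnb1 were not analysed here.

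All 26 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 9 combinations of group and title code. Empirical Bayes variances and Benjamini-Hochberg adjustment at 0.05 over all genes were used for the 10 comparisons, and SE is the moderated standard error. Tumors against neurospheres was the mean of the differences within each title code. Every p value of a gene comes from limma. The labels do not say whether arrays came from separate animals or cultures, so the p values measure only spread between arrays. That spread was pooled over all 26 arrays. Replicate numbers follow deposit order only. Groups of 2 or 3 arrays limit precision, and the drug comparisons rest on 2 untreated tumors.

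The 27 gene lists were written down before the data were examined; 522 of their 589 members were measured, and lists with at least 3 measured genes were tested. Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives; across the 10 comparisons 83 list calls passed with camera, 5 with an estimated correlation and 29 with fry. A count adjusted over the list alone uses limma p values adjusted within that list.

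Genes considered for naming were set by rule: Myc, Trp53 and Cdkn2c; the 8 largest rises and 8 largest falls past 0.05 whose arrays did not overlap within a code, without predicted genes; up to 4 members past 0.05 of each list, or the 2 largest where none passed; and genes of drug targets, transport and activation, among them Tyms, Gart, Atic, Slc19a1, Fpgs, Ggh, Dck, Cda, Rrm1, Rrm2 and Slc29a1. From these, genes that held under the alternatives were preferred in the text.

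The pipeline was tried on simulated arrays of the same layout, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. At 2-fold, limma found 67.2% for the neurosphere comparison, 73.1% for tumors against neurospheres, 61.2% for secondary tumors, 47.8% for pemetrexed, 40.3% for gemcitabine, 47.8% for the combination, and 20.9% for additivity. At 1.5-fold the share fell to 8.96% for pemetrexed, 13.4% for gemcitabine and 4.48% for the combination. A list shifted by 0.5 was found in 10 of 10 comparisons, with 1 false call. Genes were independent in the simulation, which is the easiest case for a list test. Each gene also had the same normal spread in every group. In the data the SD over genes between replicates ran from 0.294 (secondary tumor replicates 2 and 3) to 1.03 (Group3 neurosphere replicates 4 and 6). The shares found may therefore differ from those in these data.

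Shared controls were simulated 20 times with unchanged groups set against the same untreated tumors. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.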

Results

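Gene expression was measured on 26 arrays of mouse cells and tumors from a model of Group3 medulloblastoma, a childhood tumor of the cerebellum in which MYC is often overexpressed. Neurospheres, which are floating cultures of neural cells, lacked Trp53 and Cdkn2c, and those called Group3 also carried the Myc genotype. The 7 groups were Trp53 Cdkn2c neurospheres (3 arrays), Group3 neurospheres (7), untreated Group3 tumors (5), secondary Group3 tumors (3), and Group3 tumors given pemetrexed (2), gemcitabine (3) or both drugs (3). Pemetrexed is an antifolate that blocks thymidylate and purine synthesis, and gemcitabine is a nucleoside analogue that stops DNA synthesis; no dose or time was given. Array titles began with the letters dka (12 arrays) or mmm (14 arrays). Only untreated tumors and Group3 neurospheres were present under both codes, all secondary tumors and Trp53 Cdkn2c neurospheres were dka, and all drug-treated tumors were mmm. Median log2 intensity lay between 4.65 and 4.82 on every array, but the range of values differed. The dka arrays ran from 2.56 to 13.9, and mmm neurosphere replicate 7 from 2.64 to 13.7. The other mmm arrays reached as low as -0.41 and as high as 16.1. Sizes of change under the codes are therefore not directly comparable.

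The genes named in the genotype were examined in every group. Myc, read by 1 probe set, had a mean log2 intensity of 8.43 ± 0.55 (SD, n = 3) in Trp53 Cdkn2c neurospheres and 7.99 ± 0.26 (n = 3) in dka Group3 neurospheres, a difference of -0.44 (SE 0.50, limma adjusted p = 0.607). Over all 23 arrays of the Myc genotype it ranged from 6.93 to 9.48. Mycn, a Myc paralog, was read by 3 probe sets. The brightest had a mean of 4.59 ± 0.20 (n = 3) in Trp53 Cdkn2c neurospheres and lay between 12.4 and 15.3 in all 23 arrays of the Myc genotype. The remaining pair fell by 6.82 (SE 0.24) and by 3.81 (SE 0.13) on the log2 scale between the same neurosphere groups, each with a limma adjusted p of 1.08e-13 over all probe sets. They fell to means of 4.64 and 3.66, around or below the array medians, as was the brightest in Trp53 Cdkn2c neurospheres, so the sizes of these 3 differences are lower bounds. Cdkn2c stayed between 3.28 and 4.80 on all 26 arrays, around or below the array medians, so its level gave no contrast between genotypes. Trp53 was not analysed here. Whether these probe sets lie in the deleted or introduced sequences was not examined, so they do not check the genotypes.

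**Figure D1:**
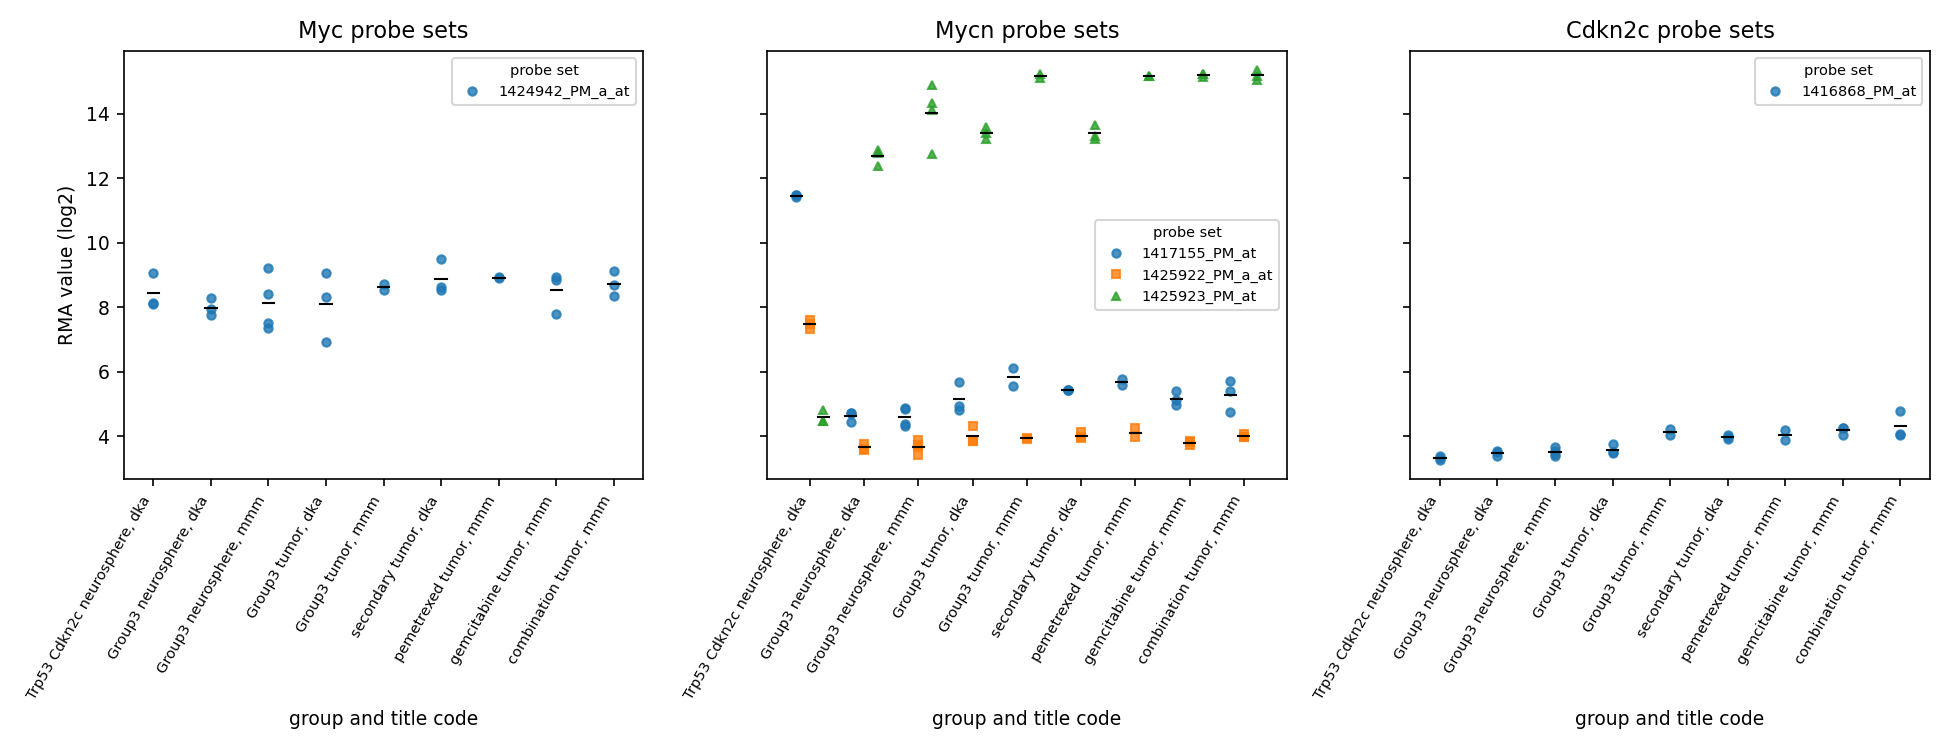
Log2 intensity of each Myc, Mycn and Cdkn2c probe set on each array (points), by group and title code, with the group mean as a black bar. The brightest Mycn probe set lay between 12.4 and 15.3 in the 23 arrays of the Myc genotype and averaged 4.59 in Trp53 Cdkn2c neurospheres.

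Group3 neurospheres were set against Trp53 Cdkn2c neurospheres, 3 dka arrays each. Genes of granule neurons, the most numerous cerebellar neurons, and of their progenitors were much lower in Group3 neurospheres. Neurod1, a transcription factor of differentiating granule neurons, fell by 8.37 on the log2 scale (SE 1.03, limma adjusted p = 7.98e-06), and Elavl3, a neuronal RNA-binding protein gene, fell by 6.29 (SE 0.47, adjusted p = 2.12e-08). Of the 18 measured genes of granule neuron differentiation, 11 fell and 7 did not pass, the same count when adjusted over the list alone. The median change was -2.09, with a camera adjusted p of 1.58e-09 (adjusted p = 0.0432 with an estimated correlation). Of 18 genes of the SHH pathway and granule progenitors, 11 fell and 3 rose (12 and 3 adjusted over the list alone). Their median was -2.32, with a camera adjusted p of 1.38e-07 (adjusted p = 0.0432 with an estimated correlation). Sfrp1, a secreted Wnt modulator, fell by 7.53 (SE 0.26, adjusted p = 1.87e-13), Atoh1, the transcription factor that specifies granule progenitors, by 5.83 (SE 0.50, adjusted p = 1.23e-07), and Barhl1, another factor of that lineage, by 5.63 (SE 0.17, adjusted p = 3.24e-14). Mycn counted among the 3 that rose, through its brightest probe set (8.09, a lower bound, SE 0.33, adjusted p = 1.59e-12), and changed by -0.85 with the mean of its probe sets (adjusted p = 0.000152).

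Markers of microglia and macrophages and of endothelium, and genes of interferon and immediate early responses, were also lower in Group3 than in Trp53 Cdkn2c neurospheres. The lymphocyte and neutrophil lists did not pass (camera adjusted p = 0.926 for each). Of 20 microglia and macrophage markers, 11 fell and 1 rose, also when adjusted over the list alone (median -1.35, camera adjusted p = 2.36e-09 and adjusted p = 0.329 with an estimated correlation). The cathepsin gene Ctss fell by 4.52 (SE 0.43, limma adjusted p = 3.30e-07) and the lysozyme gene Lyz2 by 4.45 (SE 0.39, adjusted p = 1.23e-07). Of 17 endothelial markers, 4 fell (6 adjusted over the list alone; median -0.58, camera adjusted p = 0.000223 and adjusted p = 0.521 with an estimated correlation), among them the tight junction gene Cldn5 at -2.71 (SE 0.47, adjusted p = 0.000307). Of 21 interferon response genes, 9 fell, also when adjusted over the list alone (median -0.86, camera adjusted p = 7.32e-06 and adjusted p = 0.445 with an estimated correlation), with Cxcl10 down by a log2 change of -4.35 (SE 0.75, adjusted p = 0.000281). Of 17 immediate early genes, 7 fell (10 adjusted over the list alone; median -1.57, camera adjusted p = 1.52e-05 and adjusted p = 0.445 with an estimated correlation), led by Fosb at -5.24 (SE 0.97, adjusted p = 0.000542). The immediate early median was -1.04 without Trp53 Cdkn2c neurosphere replicate 2. The haemoglobin gene Hba-a1 fell by 4.80 (SE 0.44, adjusted p = 2.63e-07). The microglia, endothelial and red blood cell lists averaged 3.99, 4.17 and 4.21 in dka Group3 neurospheres. These means lay below the array medians, so the sizes of falls in these lists may be lower bounds.

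Cholesterol synthesis genes rose in Group3 neurospheres: 10 of 17 passed, also when adjusted over the list alone, with a median of 0.90 and a camera adjusted p of 0.000264 (adjusted p = 0.521 with an estimated correlation). Nsdhl, a sterol dehydrogenase gene, rose by 1.45 (SE 0.23, limma adjusted p = 0.000103) and Sqle, the squalene epoxidase gene, by 1.24 (SE 0.19, adjusted p = 7.80e-05). Of 20 hypoxia and glycolysis genes, 6 rose and 2 fell (9 and 2 adjusted over the list alone). Their median was 1.40, with a camera adjusted p of 0.0199 (adjusted p = 0.740 with an estimated correlation). This list did not pass without Group3 neurosphere replicate 1 (adjusted p = 0.126) or 3 (adjusted p = 0.0569), and its median was 2.11 without replicate 2. Pdk1, a pyruvate dehydrogenase kinase gene, rose by 4.18 (SE 0.37, adjusted p = 1.62e-07). Of 42 DNA replication genes, 11 fell (14 adjusted over the list alone), with a median of -0.34 and a camera adjusted p of 6.94e-05 (adjusted p = 0.740 with an estimated correlation); without Group3 neurosphere replicate 2 the adjusted p was 0.0711 and the median -0.089, and without replicate 1 the median was -0.54. E2f1 fell by 1.98 (SE 0.27, adjusted p = 2.19e-05) and Mcm6 by 1.14 (SE 0.21, adjusted p = 0.000463).

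Several lists held changed genes without passing as a whole. Of 21 neural stem cell genes, 9 rose and 2 fell (9 and 3 adjusted over the list alone; median 1.17, camera adjusted p = 0.117), with Id3 at 4.81 (SE 0.82, limma adjusted p = 0.000244) and Sox21 at 4.49 (SE 0.77, adjusted p = 0.000254). Of 12 astrocyte markers, 3 rose and 1 fell (6 and 1 adjusted over the list alone; median 1.86, camera adjusted p = 0.107), with Aldoc at 7.29 (SE 1.08, adjusted p = 6.03e-05) and Acsbg1 at 4.68 (SE 0.62, adjusted p = 1.99e-05). Of 33 MYC targets and ribosome biogenesis genes, 5 rose and 2 fell, also when adjusted over the list alone (median 0.13, camera adjusted p = 0.477): Nop16 rose by 1.51 (SE 0.22, adjusted p = 6.45e-05) and Odc1, of polyamine synthesis, fell by 0.83 (SE 0.15, adjusted p = 0.000499). In the folate and nucleotide synthesis list, 4 of 24 genes rose (2 adjusted over the list alone; median 0.20, camera adjusted p = 0.225), including Slc19a1, the reduced folate carrier (0.99, SE 0.21, adjusted p = 0.00149). Slc29a1, a nucleoside transporter that carries gemcitabine, fell by 1.75 (SE 0.27, adjusted p = 7.94e-05), while its list of 22 transport and salvage genes had 4 genes up and 2 down (median 0.074, camera adjusted p = 0.926). Otx2, a Group 3 medulloblastoma gene, fell by 5.94 (SE 0.74, adjusted p = 8.74e-06), and the 18 genes of its list had a median of 0.057 and a mean of -0.31 (camera adjusted p = 0.572). Outside the lists, the largest rises included the desaturase gene Scd1 (6.01, SE 0.48, adjusted p = 3.77e-08), Skap2 (5.85, SE 0.58, adjusted p = 6.48e-07), Igfbp2 (5.70, SE 0.44, adjusted p = 2.89e-08) and the homeobox gene Hoxa5 (5.44, SE 0.51, adjusted p = 3.18e-07).

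In all, limma called 3865 of 17097 genes in this comparison, 2288 higher and 1577 lower in Group3 neurospheres, of which 1386 and 1006 changed at least 2-fold. At an unadjusted p under 0.05 there were 5671 genes, against 855 that chance gives.

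Untreated Group3 tumors (5 arrays) were set against Group3 neurospheres (7 arrays) within each title code and averaged over the codes. Tumors carried far more signal from genes of macrophages, vessels, connective tissue and neurons. Of 20 microglia and macrophage markers, 19 rose, also when adjusted over the list alone. Their median was 2.32 with a camera adjusted p of 3.09e-20 (adjusted p = 0.0916 with an estimated correlation). The list rose under both codes, by a median of 1.47 in dka (camera adjusted p = 3.63e-11) and 3.34 in mmm (4.59e-23). The codes differed by a median of 1.56 (camera adjusted p = 9.67e-09 and adjusted p = 0.302 with an estimated correlation). The list averaged 3.99 in dka and 3.94 in mmm neurospheres, below the array medians, so the sizes of its rises may be lower bounds. The complement gene C1qb rose by 4.92 (SE 0.25, limma adjusted p = 2.06e-10, with 4.06 in dka and 5.79 in mmm) and Ctss by 5.46 (SE 0.31, adjusted p = 7.87e-10, with 4.08 and 6.83). Of 17 endothelial markers, 16 rose (17 adjusted over the list alone). Their median was 1.38 with a camera adjusted p of 4.41e-14 (adjusted p = 0.0945 with an estimated correlation). Within the codes it was 1.27 in dka and 1.86 in mmm. Vwf, the von Willebrand factor gene of endothelium, rose by 2.57 (SE 0.25, adjusted p = 3.37e-07, with 2.63 and 2.51). Of 17 fibroblast, pericyte and matrix genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone). Their median was 1.03 with a camera adjusted p of 1.39e-05 (adjusted p = 0.209 with an estimated correlation); the medians were 1.09 in dka and 1.54 in mmm. The pericyte gene Rgs5 rose by 5.77 (SE 0.36, adjusted p = 2.63e-09, with 5.70 and 5.84).

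Granule neuron genes were higher in tumors than in Group3 neurospheres. Of 18 genes of granule neuron differentiation, 9 rose and 1 fell, also when adjusted over the list alone (median 1.68, camera adjusted p = 2.55e-06 and adjusted p = 0.0945 with an estimated correlation), with medians of 1.27 in dka and 2.40 in mmm. Neurod1 rose by 6.93 (SE 0.75, limma adjusted p = 1.60e-06, with 7.83 in dka and 6.03 in mmm) and Rbfox3, the NeuN gene, by 5.88 (SE 0.47, adjusted p = 3.80e-08, with 5.09 and 6.67). The list of other mature neurons had 8 of 15 genes up (11 adjusted over the list alone; median 1.36, camera adjusted p = 9.35e-06 and adjusted p = 0.191 with an estimated correlation). Its median was 3.39 in mmm (adjusted p = 8.44e-09) and 0.15 in dka (0.282), and the codes differed with a camera adjusted p of 9.62e-06 (adjusted p = 0.302 with an estimated correlation). Nefl, a neurofilament gene, rose by 5.08 (SE 0.88, adjusted p = 0.000244, with 4.67 and 5.48). Of 13 oligodendrocyte markers, 8 rose (10 rose and 1 fell adjusted over the list alone; median 1.83, camera adjusted p = 0.000374 and adjusted p = 0.459 with an estimated correlation). The median was 1.52 in dka (adjusted p = 0.148) and 2.65 in mmm (9.76e-06), and the codes differed with a camera adjusted p of 0.00379 (adjusted p = 0.492 with an estimated correlation). Mbp, the myelin basic protein gene, rose by 5.59 (SE 0.72, adjusted p = 1.10e-05, with 4.01 and 7.16). Interferon response genes had 11 of 21 up (13 adjusted over the list alone; median 0.93, camera adjusted p = 1.15e-05 and adjusted p = 0.250 with an estimated correlation), with a median of 0.45 in dka (adjusted p = 0.108) and 1.97 in mmm (1.07e-07). For this list the codes differed with a camera adjusted p of 0.000558 (adjusted p = 0.430 with an estimated correlation). Cxcl10 rose by 3.83 (SE 0.55, adjusted p = 3.59e-05, with 3.75 and 3.92). Of 4 red blood cell genes, Hba-a1 rose by 5.54 (SE 0.32, adjusted p = 1.04e-09, with 3.35 and 7.73), with 2 up adjusted over the list alone. The list's camera adjusted p of 0.0442 (adjusted p = 0.191 with an estimated correlation) was lost without Group3 tumor replicate 1 (0.0594) or 5 (0.0623), or Group3 neurosphere replicate 1 (0.0516), 2 (0.0551) or 4 (0.0894).

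Lists of growth and cell division had different medians under the title codes. Of 33 MYC targets and ribosome biogenesis genes, 13 rose in tumors (16 adjusted over the list alone; median 0.32, camera adjusted p = 1.35e-05 and adjusted p = 0.250 with an estimated correlation), but the median was 0.73 in dka (adjusted p = 6.73e-14) and -0.090 in mmm (0.838). Odc1 rose by 1.64 (SE 0.11, limma adjusted p = 5.92e-09, with 1.69 and 1.59). Of 30 mitosis genes, 9 fell, also when adjusted over the list alone (median -0.35, camera adjusted p = 0.000766 and adjusted p = 0.594 with an estimated correlation), with a median of 0.040 in dka (adjusted p = 0.592) and -0.83 in mmm (3.92e-08). Ccnb2, a mitotic cyclin gene, fell by 1.33 (SE 0.21, adjusted p = 0.000128), with -0.41 in dka and -2.25 in mmm. DNA replication genes did not pass over both codes (median -0.0016, mean 0.095, camera adjusted p = 0.277); they rose in dka (0.46, adjusted p = 2.88e-06) and fell in mmm (-0.54, adjusted p = 0.0203). Folate and nucleotide synthesis genes (median 0.14, camera adjusted p = 0.468) rose in dka (0.48, adjusted p = 0.000163) and fell in mmm (-0.35, adjusted p = 0.0129), and DNA repair genes (median -0.16, camera adjusted p = 0.277) rose in dka (0.38, adjusted p = 0.0367) and fell in mmm (-0.50, adjusted p = 7.60e-05). The difference between the codes passed camera for DNA replication (adjusted p = 2.78e-09), MYC targets (1.51e-10), mitosis (1.61e-08), folate (7.86e-09) and repair (6.21e-08). With an estimated correlation none of these passed (adjusted p = 0.365, 0.209, 0.353, 0.209 and 0.341). Over all probe sets, the mean of the dka neurospheres and of mmm neurosphere replicates 4 to 6 differed by an SD of 0.132.

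Cholesterol synthesis genes were lower in tumors: 12 of 17 fell (13 fell and 1 rose adjusted over the list alone), with a median of -0.85 and a camera adjusted p of 1.39e-05 (adjusted p = 0.250 with an estimated correlation), and the list fell in dka (-0.46, adjusted p = 0.0161) and mmm (-0.93, adjusted p = 8.47e-06). For cholesterol synthesis the codes differed by a median of -0.70 (camera adjusted p = 0.0315 and adjusted p = 0.572 with an estimated correlation). Cyp51 fell by 1.01 (SE 0.16, limma adjusted p = 9.34e-05), with -0.59 in dka and -1.44 in mmm. Of 19 genes of the unfolded protein and amino acid response, 8 fell, also when adjusted over the list alone (median -0.47, camera adjusted p = 0.0104 and adjusted p = 0.209 with an estimated correlation), with -0.67 in mmm (adjusted p = 0.00140) and -0.088 in dka (0.499). The codes differed in this list with a camera adjusted p of 0.0127 (adjusted p = 0.302 with an estimated correlation). It was lost without the dimmest genes (adjusted p = 0.0590). Psph, of serine synthesis, fell by 1.42 (SE 0.19, adjusted p = 2.01e-05), with -1.02 and -1.82. Of 21 neural stem cell genes, 9 fell and 2 rose, also when adjusted over the list alone (median -1.71, camera adjusted p = 0.0442 and adjusted p = 0.585 with an estimated correlation), with -2.16 in dka (adjusted p = 0.00120) and -0.37 in mmm (0.688). The stem cell difference between the codes had a camera adjusted p of 0.0157 (adjusted p = 0.437 with an estimated correlation). The call over both codes was lost without Group3 tumor replicate 2 (adjusted p = 0.117, median -1.05) or Group3 neurosphere replicate 2 (0.0569), 5 (0.0881), 6 (0.0668) or 7 (0.0502). Hes1, a Notch target that holds progenitors undifferentiated, fell by 2.88 (SE 0.37, adjusted p = 1.15e-05), with -3.10 and -2.65, and Sox21 fell by 3.75 (SE 0.56, adjusted p = 5.88e-05), with -3.88 and -3.61.

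The remaining lists did not pass in tumors against neurospheres. The camera adjusted p was 0.320 for nucleoside transport and salvage, 0.467 for p53 target genes (4 up and 2 down of 23), 0.483 for the SHH pathway, 0.441 for the human Group 3 and photoreceptor list, 0.281 for the oncofetal list (median -0.0093, mean 0.55), 0.845 for lymphocytes and natural killer cells, 0.277 for astrocytes (-0.57 in dka, adjusted p = 0.258, and 1.89 in mmm, 0.00186), 0.254 for neutrophils, 0.0643 for hypoxia and glycolysis, 0.270 for immediate early genes and 0.886 for apoptosis (5 up and 5 down of 16). The codes differed for astrocytes by a median of 3.03 (camera adjusted p = 6.08e-05 and adjusted p = 0.353 with an estimated correlation). Immediate early genes had a median of 0.11 in dka (camera adjusted p = 0.531) and -1.07 in mmm (0.0162). For them the codes differed by a median of -1.54 (camera adjusted p = 0.00729 and adjusted p = 0.492 with an estimated correlation). Single members rose all the same, among them Npr3 (3.59, SE 0.51, limma adjusted p = 3.16e-05, with 3.62 in dka and 3.57 in mmm), a marker of human Group 3 tumors, and the fetal growth factor gene Igf2 (4.22, SE 0.52, adjusted p = 6.38e-06, with 5.39 and 3.04). Of the drug genes, Fpgs, which polyglutamates antifolates, rose by 0.97 (SE 0.17, adjusted p = 0.000287, with 1.45 and 0.48), and Ggh, which reverses that step, fell by 0.59 (SE 0.15, adjusted p = 0.00558), with -0.65 and -0.53. Slc19a1 was higher in dka tumors (0.95, adjusted p = 0.00293) and lower in mmm tumors (-0.83, adjusted p = 0.00961), a difference with an adjusted p of 0.00257. Myc differed by 0.30 (SE 0.36, adjusted p = 0.597, with 0.12 and 0.49). Cdkn2c differed by 0.37 (SE 0.11, adjusted p = 0.0197, with 0.10 and 0.63), a call lost without Group3 tumor replicate 3 (adjusted p = 0.0525) or 5 (0.103). Its level lay around or below the array medians on every array, so this call is no clear difference in expression. The steepest falls outside the lists were those of Pipox (-5.14, SE 0.28, adjusted p = 5.17e-10, with -4.97 and -5.32) and Sned1 (-4.71, SE 0.39, adjusted p = 6.13e-08, with -3.94 and -5.47).

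In all, limma called 4611 genes, 2151 higher and 2460 lower in tumors, and 6291 genes had an unadjusted p under 0.05 against 855 by chance. Taken alone, dka gave 3172 genes and mmm 3782, and 1567 genes differed between the codes. Untreated tumors differed between the codes at 3711 genes, while for Group3 neurospheres limma called 0 genes between the codes, with 39 at an unadjusted p under 0.05 against 855 by chance.

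Secondary tumors (3) were set against primary tumors (3), all dka. Rlf, Dlx1 and Ramp2 were among the genes that were higher in secondary tumors. Rlf, a zinc finger gene next to Mycl, was 13.2-fold higher in secondary tumors (log2 3.72, SE 0.26, limma adjusted p = 2.21e-07). The homeobox gene Dlx1 rose by 3.52 (SE 0.59, adjusted p = 0.00746), Ramp2, a receptor accessory protein of vessels, by 2.53 (SE 0.33, adjusted p = 0.000992), Bclaf1 by 2.05 (SE 0.26, adjusted p = 0.000963) and the interferon gamma receptor gene Ifngr2 by 1.94 (SE 0.35, adjusted p = 0.0117). The macrophage lectin gene Clec10a fell by 3.06 (SE 0.40, adjusted p = 0.000992) and the homeobox gene Irx2 by 3.02 (SE 0.48, adjusted p = 0.00662). Each of the 7 called genes named here passed whichever of the 6 arrays was left out, but genes that held were preferred for naming. Secondary tumor replicates 2 and 3 correlated at r = 0.993, and replicate 1 with either at 0.961. Leaving out 1 of that close pair therefore kept an array much like it. Of the 20 called genes considered for naming, 7, 7 and 4 did not pass without secondary tumor replicates 1, 2 and 3. With only the arrays compared in the fit 1 gene passed, Dlx1.

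Mitosis genes were somewhat higher and interferon response genes lower in secondary tumors. Of 30 mitosis genes, 27 had positive values and Anln rose (0.75, SE 0.16, limma adjusted p = 0.0363), the same count adjusted over the list alone. The list had a median of 0.32 and a camera adjusted p of 6.32e-07 (adjusted p = 0.761 with an estimated correlation). Anln did not pass without Group3 tumor replicate 2 or 3 or without any of the secondary tumors. Of 21 interferon response genes, 20 had negative values and Xaf1 fell by 1.83 (SE 0.38, adjusted p = 0.0309, with 4 genes adjusted over the list alone). The list had a median of -0.96 and a camera adjusted p of 5.60e-06 (adjusted p = 0.761 with an estimated correlation). Its median was -1.51 without Group3 tumor replicate 1 and -0.61 without replicate 2 (adjusted p = 0.00548). Oligodendrocyte markers had negative values in all 13 genes (median -1.79, camera adjusted p = 0.000414 and adjusted p = 0.761 with an estimated correlation), 4 of them at an unadjusted p under 0.05. Mbp changed by -2.60 (SE 0.98, adjusted p = 0.261); without Group3 tumor replicate 3 the median was -0.33 (adjusted p = 0.477). Microglia and macrophage markers had a median of 0.51 (camera adjusted p = 0.000103 and adjusted p = 0.761 with an estimated correlation), with 4 of 20 up and 1 down at an unadjusted p under 0.05; without secondary tumor replicate 2 the median was 0.21 (adjusted p = 0.169). DNA repair (median 0.19, camera adjusted p = 0.0171 and adjusted p = 0.792 with an estimated correlation) and DNA replication (0.091, 0.0421 and adjusted p = 0.912 with an estimated correlation) passed by less. DNA repair was lost without Group3 tumor replicate 1 (0.0627) or 3 (0.0798) or secondary tumor replicate 2 (0.270) or 3 (0.201), and DNA replication without Group3 tumor replicate 1 (0.323) or secondary tumor replicate 2 (0.278) or 3 (0.138). The median of DNA replication was 0.18 without Group3 tumor replicate 2 and 0.24 without secondary tumor replicate 1, and that of DNA repair was 0.38 without the latter. Rad18 of the repair list rose by 1.39 (SE 0.25, adjusted p = 0.0130), a call lost without Group3 tumor replicate 3 or secondary tumor replicate 1. Myc differed by 0.78 (SE 0.50, adjusted p = 0.561).

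Over all genes limma called 92, 45 higher and 47 lower, with 2175 at an unadjusted p under 0.05. The count was 215 without Group3 tumor replicate 1, 38 without Group3 tumor replicate 2, and 53 and 59 without secondary tumor replicates 2 and 3.

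The drug groups were set against the 2 untreated mmm tumors. In tumors given pemetrexed (2), genes of DNA replication, repair and mitosis were higher than in untreated tumors. Markers of neurons, astrocytes and oligodendrocytes were lower. All 27 DNA repair genes had positive values (median 0.51, camera adjusted p = 5.21e-10 and adjusted p = 0.315 with an estimated correlation), as did 41 of 42 DNA replication genes (median 0.43, adjusted p = 1.17e-11 and adjusted p = 0.315 with an estimated correlation) and all 30 mitosis genes (median 0.49, adjusted p = 1.52e-09 and adjusted p = 0.315 with an estimated correlation). The mitosis median was 0.31 without pemetrexed replicate 1. The replication, repair and mitosis lists held 10, 7 and 3 genes at an unadjusted p under 0.05; none passed over all genes or adjusted over the list alone. Fancd2, of the Fanconi repair pathway, differed by 1.01 (SE 0.37), Kif23, a kinesin of cell division, by 1.05 (SE 0.38) and Prim1, a primase subunit gene, by 0.86 (SE 0.30). Folate and nucleotide synthesis genes had a median of 0.34 (22 of 24 positive, camera adjusted p = 2.54e-05 and adjusted p = 0.315 with an estimated correlation), with Slc19a1 at 0.69 (SE 0.25) and Tyms, the thymidylate synthase gene that pemetrexed inhibits, at 0.73 (SE 0.41). MYC targets had a median of 0.29 (adjusted p = 1.07e-06 and adjusted p = 0.315 with an estimated correlation) and cholesterol synthesis 0.29 (adjusted p = 0.00963 and adjusted p = 0.641 with an estimated correlation).

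The brain cell markers moved the other way in pemetrexed-treated tumors. All 15 mature neuron markers had negative values (median -1.39, camera adjusted p = 2.65e-09 and adjusted p = 0.235 with an estimated correlation), as did all 12 astrocyte markers (median -0.86, adjusted p = 0.000322 and adjusted p = 0.463 with an estimated correlation) and 12 of 13 oligodendrocyte markers (median -1.29, adjusted p = 0.000742 and adjusted p = 0.567 with an estimated correlation). Calb1, a Purkinje cell gene, differed by -2.84 (SE 1.23) and Gjb6, an astrocyte connexin gene, by -2.38 (SE 0.87). Interferon response genes were lower (median -0.67, adjusted p = 4.03e-08 and adjusted p = 0.315 with an estimated correlation), as were endothelial markers (median -0.22, adjusted p = 0.000666 and adjusted p = 0.567 with an estimated correlation), with Ly6c1 at -1.60 (SE 0.49). Adjusted over the list alone, 1 mature neuron gene and 1 red blood cell gene passed, both lower. Without Group3 tumor replicate 4 the oligodendrocyte list did not pass (median -0.59). Without Group3 tumor replicate 5 the endothelial (median -0.0021) and cholesterol lists did not pass. Without pemetrexed replicate 1 the astrocyte list did not pass (median -0.44), and without pemetrexed replicate 2 the cholesterol list did not. The interferon median was -0.44 without Group3 tumor replicate 4 and -0.45 without pemetrexed replicate 1, and the oligodendrocyte median -1.94 without Group3 tumor replicate 5. Without pemetrexed replicates 1 and 2 the endothelial median was -0.14 and -0.39, and without replicate 2 the astrocyte median was -1.67. Limma called 0 genes, with 807 at an unadjusted p under 0.05 where chance gives 855, and a smallest adjusted p of 0.0837. The count was 10 without Group3 tumor replicate 4, 4 without Group3 tumor replicate 5, 2 without pemetrexed replicate 1, and 201 with array weights.

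Gemcitabine-treated tumors (3) differed from untreated tumors in much the same lists. All 27 DNA repair genes had positive values (median 0.52, camera adjusted p = 2.38e-08 and adjusted p = 0.401 with an estimated correlation), with Palb2 at 1.11 (SE 0.36) and Rad51ap1 at 0.94 (SE 0.30), both genes of homologous recombination. Mitosis genes had a median of 0.55 (27 of 30 positive, adjusted p = 1.32e-08 and adjusted p = 0.401 with an estimated correlation), with 14 at an unadjusted p under 0.05, and DNA replication genes 0.37 (38 of 42 positive, adjusted p = 3.99e-06 and adjusted p = 0.662 with an estimated correlation), with Prim1 at 0.92 (SE 0.28). Folate and nucleotide synthesis had a median of 0.36 (adjusted p = 0.000166 and adjusted p = 0.401 with an estimated correlation) and MYC targets 0.25 (adjusted p = 0.000659 and adjusted p = 0.531 with an estimated correlation). Among the lower lists, mature neurons had a median of -1.19 (14 of 15 negative, adjusted p = 2.58e-07 and adjusted p = 0.401 with an estimated correlation), astrocytes -1.33 (0.000728 and adjusted p = 0.531 with an estimated correlation), oligodendrocytes -1.11 (0.00332 and adjusted p = 0.710 with an estimated correlation), granule neuron differentiation -0.54 (0.00118 and adjusted p = 0.401 with an estimated correlation) and interferon response -0.65 (3.99e-06 and adjusted p = 0.401 with an estimated correlation). Endothelial (-0.20, 0.0141 and adjusted p = 0.769 with an estimated correlation) and microglia markers (-0.28, 0.0266 and adjusted p = 0.773 with an estimated correlation) passed by less. Gjb6 differed by -2.04 (SE 0.80) and Stmn2 by -2.69 (SE 1.12). Without gemcitabine replicate 2 the astrocyte (median -0.49, adjusted p = 0.309), oligodendrocyte (-0.58, 0.180), endothelial (-0.016, 0.180) and microglia (-0.052, 0.747) lists did not pass. The oligodendrocyte list was also lost without Group3 tumor replicate 4 (median -0.55). The endothelial and microglia lists were lost without Group3 tumor replicate 5, where the endothelial median turned to 0.092. Without gemcitabine replicate 3 the lists moved further: mature neurons had a median of -2.23, astrocytes -2.30, oligodendrocytes -2.16, interferon response -1.12, microglia -0.57, DNA replication 0.61, folate 0.54 and MYC targets 0.37. Without replicate 2 DNA replication had a median of 0.23 and interferon response -0.38, and without replicate 1 the endothelial median was -0.080. The interferon median was -0.39 without Group3 tumor replicate 4, and the oligodendrocyte median -1.95 without replicate 5.

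Adjusted over the list alone, 1 replication gene and 1 endothelial gene passed for gemcitabine. Limma called 0 genes, with 1472 at an unadjusted p under 0.05 and a smallest adjusted p of 0.181. A single array decided this count: without gemcitabine replicate 3, 324 genes passed. It was 7 and 6 without Group3 tumor replicates 4 and 5, 2 without gemcitabine replicate 1, and 3922 with array weights.

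The combination of both drugs was represented by 3 tumors. Gli1, the transcription factor and target of the SHH pathway, was 12.3-fold higher than in untreated tumors (log2 3.62, SE 0.64, limma adjusted p = 0.0446) and the ectonucleotidase gene Entpd2 15.3-fold higher (3.93, SE 0.69, adjusted p = 0.0446). Septin8 rose by 2.57 (SE 0.48, adjusted p = 0.0463), Pald1 by 2.33 (SE 0.41, adjusted p = 0.0446) and Dlc1 by 1.29 (SE 0.23, adjusted p = 0.0446). The amino acid transporter gene Slc6a20a fell by 2.63 (SE 0.42, adjusted p = 0.0446) and the cadherin gene Cdh9 by 2.25 (SE 0.41, adjusted p = 0.0446). None of these genes passed without combination replicate 1 or 3 or without Group3 tumor replicate 5, and of the 7 only Slc6a20a and Cdh9 passed without Group3 tumor replicate 4. The adjusted p of Gli1 was 0.248 and 0.129 without combination replicates 1 and 3, and 0.188 and 0.224 without Group3 tumor replicates 4 and 5. Slc6a20a and Cdh9 changed by -1.50 and -1.27 without Group3 tumor replicate 5. Limma called 13 genes, 9 higher and 4 lower, with 1350 at an unadjusted p under 0.05. The count was 0 without combination replicate 1 (0 also without replicate 3), 33 without replicate 2, 6 without Group3 tumor replicate 5, 0 with only the compared arrays in the fit and 523 with array weights.

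The combination shared the list pattern of the single drugs. DNA repair genes had a median of 0.58 (all 27 positive, camera adjusted p = 6.32e-10 and adjusted p = 0.358 with an estimated correlation), DNA replication 0.46 (adjusted p = 2.23e-09 and adjusted p = 0.462 with an estimated correlation), mitosis 0.40 (adjusted p = 8.68e-07 and adjusted p = 0.488 with an estimated correlation), folate and nucleotide synthesis 0.30 (adjusted p = 0.000272 and adjusted p = 0.459 with an estimated correlation) and MYC targets 0.22 (adjusted p = 0.000101 and adjusted p = 0.459 with an estimated correlation). Tk1, the salvage thymidine kinase gene, differed by 1.38 (SE 0.44, limma adjusted p = 0.425), Kif23 by 1.23 (SE 0.34, adjusted p = 0.315) and Slc19a1 by 0.68 (SE 0.23, adjusted p = 0.478). The nucleoside transport and salvage list, which holds Tk1, did not pass (11 of 22 positive, median 0.0033, camera adjusted p = 0.632). Nor did it for pemetrexed (camera adjusted p = 0.576) or gemcitabine (0.84) against untreated tumors. Mature neuron markers had a median of -1.55 (all 15 negative, adjusted p = 1.08e-07 and adjusted p = 0.205 with an estimated correlation). Oligodendrocytes had a median of -1.48 (adjusted p = 0.000272 and adjusted p = 0.489 with an estimated correlation), astrocytes -1.07 (0.00422 and adjusted p = 0.511 with an estimated correlation), granule neurons -0.67 (0.00275 and adjusted p = 0.459 with an estimated correlation), endothelium -0.41 (0.000568 and adjusted p = 0.489 with an estimated correlation), interferon response -0.36 (0.00513 and adjusted p = 0.549 with an estimated correlation) and microglia -0.25 (0.0372 and adjusted p = 0.695 with an estimated correlation). Red blood cell genes were higher (median 0.50, adjusted p = 0.00275 and adjusted p = 0.102 with an estimated correlation), 2 of 4 adjusted over the list alone, with the haemoglobin gene Hba-a2 at 0.61 (SE 0.22, adjusted p = 0.526). Adjusted over the list alone, 2 endothelial genes, 1 mature neuron gene, 1 SHH gene and 1 neural stem cell gene also passed. Without Group3 tumor replicate 4 the astrocyte, oligodendrocyte and interferon lists did not pass (medians -0.64, -0.67 and -0.17). Without Group3 tumor replicate 5 the microglia list did not pass. Without combination replicate 1 the astrocyte (median -0.50, adjusted p = 0.138), interferon (-0.17, 0.170) and granule neuron (-0.32, 0.109) lists did not pass. Without combination replicate 3 the microglia median was 0.048. Without combination replicate 1 the medians of folate, mitosis, MYC targets and oligodendrocytes were 0.19, 0.22, 0.11 and -0.84. Without replicate 2 microglia had a median of -0.56 and interferon response -0.60, and without Group3 tumor replicate 5 endothelium had -0.20 and oligodendrocytes -2.24.

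With group and title code as additive terms, the folate and MYC target medians in the combination turned to -0.048 and -0.066. The microglia median there turned to 0.17. In pemetrexed the folate median turned to -0.035, and in gemcitabine the folate, MYC target and microglia medians to -0.017, -0.027 and 0.25. In that fit the untreated dka tumors also enter the control. Their folate, MYC target and microglia lists averaged 9.14, 10.2 and 5.95, against 8.24, 9.37 and 7.44 in untreated mmm tumors.

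Amounts of brain cell signal varied between the drug-series tumors. The mean of the neuron, astrocyte and oligodendrocyte markers was 8.94 and 8.13 in the untreated tumors, 8.85 in gemcitabine replicate 3, and between 5.98 and 8.01 in the other 7 treated tumors. The mean of the DNA replication genes was 8.26 in each untreated tumor, 8.22 in gemcitabine replicate 3, and between 8.56 and 8.92 in the others. With the marker mean as a covariate in the 10 tumor arrays, an alternative chosen after the data were seen, the treated tumors' difference in the replication list went from 0.42 (SE 0.17) to 0.15 (SE 0.077).

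**Figure D2:**
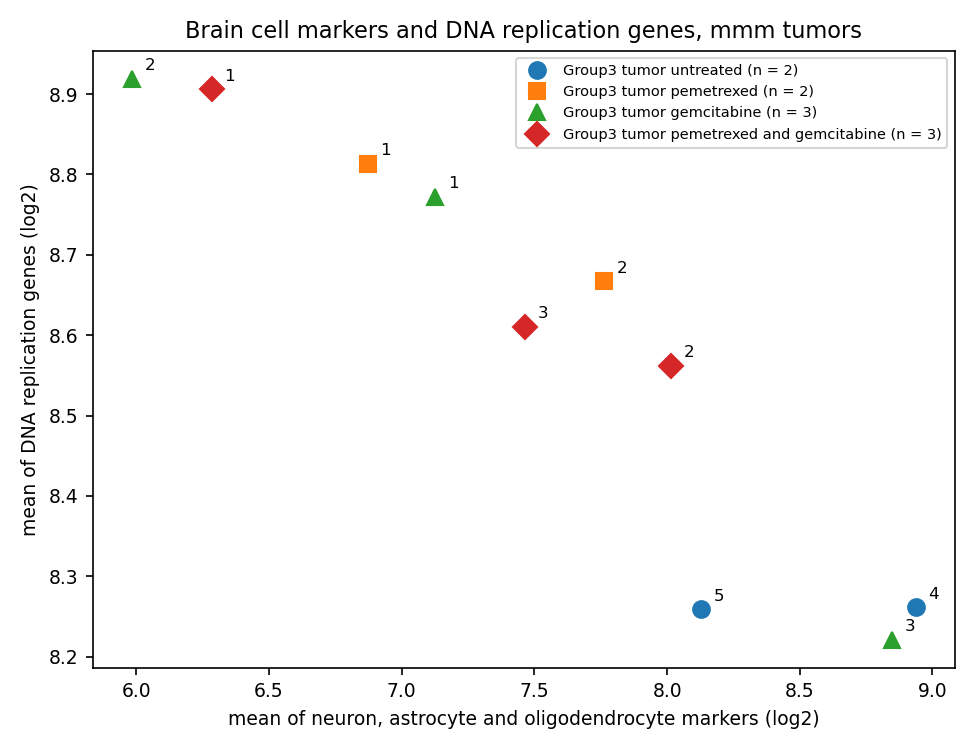
Mean log2 intensity of the neuron, astrocyte and oligodendrocyte markers (x axis) against that of the DNA replication genes (y axis) in the 10 mmm tumors, each point labelled by replicate and coloured by group. The untreated tumors and gemcitabine replicate 3 had marker means of 8.13 to 8.94 and replication means of 8.22 to 8.26.

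Myc and the 9 measured drug genes (Tyms, Gart, Slc19a1, Fpgs, Ggh, Dck, Rrm1, Rrm2 and Slc29a1) were followed in the 3 comparisons with untreated tumors. Of the 30 values, 0 passed limma's test, and 14 changed sign in at least 1 alternative setting, so those are not given singly. Slc19a1, Tyms and Rrm1 kept their sign in all settings and all 3 comparisons; Rrm1, a subunit of the ribonucleotide reductase that gemcitabine inhibits, differed by 0.42 (SE 0.32), 0.39 (SE 0.29) and 0.49 (SE 0.29) for pemetrexed, gemcitabine and the combination. Atic and Cda were not analysed here.

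The 3 drug comparisons shared their 2 untreated tumors, which alone makes them alike. Across genes, which are not independent replicates, pemetrexed and gemcitabine changes correlated at r = 0.839 where unchanged groups simulated against the same controls gave 0.553, pemetrexed and combination at 0.815 (simulated 0.548), and gemcitabine and combination at 0.775 (simulated 0.599). The covariances were 0.177, 0.185 and 0.178 against simulated values of 0.0978, 0.0970 and 0.0970. The controls were too few to split, and the simulation drew each gene independently. It therefore cannot tell how much of the excess, or whether all of it, comes from the controls.

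Red blood cell genes set the combination apart from either drug alone. Against pemetrexed, their median was 0.78 (camera adjusted p = 1.08e-06 and adjusted p = 0.000906 with an estimated correlation), with Alas2, the erythroid haem synthesis gene, at 1.25 (SE 0.22, limma adjusted p = 0.0780) and Hba-a1 at 2.36 (SE 0.50, adjusted p = 0.430), both passing adjusted over the list alone. Against gemcitabine the median was 0.68 (camera adjusted p = 9.07e-05 and adjusted p = 0.00536 with an estimated correlation), with Alas2 at 0.89 (SE 0.19, adjusted p = 0.225), the only 1 of 4 to pass adjusted over the list alone. Gli1 differed by 2.32 (SE 0.64) from pemetrexed and by 2.60 (SE 0.57, adjusted p = 0.225) from gemcitabine, and Hes1 by 1.75 (SE 0.57) and 2.10 (SE 0.51, adjusted p = 0.351).

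Other lists separated the combination from single drugs only weakly. Against pemetrexed, interferon response (median 0.31, camera adjusted p = 0.00759 and adjusted p = 0.911 with an estimated correlation) and immediate early genes (0.57, 0.0289 and adjusted p = 0.911 with an estimated correlation) were higher and cholesterol synthesis lower (-0.24, 0.0257 and adjusted p = 0.911 with an estimated correlation). Leaving out pemetrexed replicate 1 ended the interferon (0.523) and immediate early (0.312) calls, pemetrexed replicate 2 the cholesterol (0.247) and immediate early (0.0578) calls, and combination replicate 2 the interferon (0.834) and cholesterol (0.767) calls, and turned the immediate early median to -0.0039. The interferon median was 0.50 without pemetrexed replicate 2 and 0.56 without combination replicate 1, and the cholesterol median -0.40 without the latter. Against gemcitabine, the SHH (median 0.22), neural stem cell (0.097) and immediate early (0.52) lists each had a camera adjusted p of 0.0463 (adjusted p = 0.954 with an estimated correlation for each), with 1 gene of the SHH and 1 of the stem cell list passing adjusted over the list alone. Leaving out gemcitabine replicate 1 or 2 or combination replicate 2 ended the stem cell (0.111, 0.286 and 0.0716) and immediate early (0.109, 0.183 and 0.970) calls, gemcitabine replicate 3 the SHH call (0.175), and combination replicate 3 the SHH (0.207) and stem cell (0.211) calls. The stem cell median was 0.29 without gemcitabine replicate 3 or combination replicate 1, the SHH median 0.41 without combination replicate 1, and the immediate early median 0.78 without combination replicate 3. Limma called 0 genes against pemetrexed (427 at an unadjusted p under 0.05, 2 with a trended and robust variance) and 0 against gemcitabine (898, and 246 with array weights). The pemetrexed count was 3 without pemetrexed replicate 1, and 5 and 1 without combination replicates 2 and 3; the gemcitabine count was 32 without gemcitabine replicate 3 and 15 without combination replicate 2.

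Departure from additivity was tested as the combination minus pemetrexed minus gemcitabine plus untreated. The untreated tumors enter this contrast with the opposite sign to that in the comparisons with them, so opposite directions in the comparisons and the departure are no separate result. Mitosis genes departed by a median of -0.59 (all 30 negative, camera adjusted p = 8.59e-08 and adjusted p = 0.613 with an estimated correlation), DNA repair by -0.52 (2.13e-05 and adjusted p = 0.613 with an estimated correlation), DNA replication by -0.38 (3.40e-05 and adjusted p = 0.646 with an estimated correlation), folate and nucleotide synthesis by -0.39 (0.00120 and adjusted p = 0.613 with an estimated correlation), MYC targets by -0.29 (0.00119 and adjusted p = 0.613 with an estimated correlation) and cholesterol synthesis by -0.43 (0.00195 and adjusted p = 0.626 with an estimated correlation). Interferon response departed by 1.14 (all 21 positive, 6.08e-08 and adjusted p = 0.341 with an estimated correlation), mature neurons by 0.95 (1.79e-05 and adjusted p = 0.341 with an estimated correlation), astrocytes by 1.12 (0.00148 and adjusted p = 0.613 with an estimated correlation), neural stem cells by 0.24 (0.0395 and adjusted p = 0.646 with an estimated correlation) and red blood cells by 0.61 (0.00112 and adjusted p = 0.0461 with an estimated correlation), with 2 red blood cell genes and 1 granule neuron gene passing adjusted over the list alone. Hba-a1 departed by 2.95 (SE 0.70, limma adjusted p = 0.686) and Pole, a DNA polymerase gene, by -1.11 (SE 0.32, adjusted p = 0.857). The astrocyte list did not pass without pemetrexed replicate 1 (0.0829) or gemcitabine replicate 2 (0.210). The stem cell list did not pass without Group3 tumor replicate 5 (0.0630), pemetrexed replicate 1 (0.0683) or 2 (0.0522), gemcitabine replicate 1 (0.0535) or 2 (0.210), or combination replicate 3 (0.147). Its median was 0.13 without Group3 tumor replicate 4 and 0.38 without combination replicate 1. The mature neuron departure was 1.45 without Group3 tumor replicate 5, 1.66 without pemetrexed replicate 2, 1.99 without gemcitabine replicate 3 and 1.68 without combination replicate 1. The astrocyte departure was 1.87, 2.04 and 1.73 without the last 3 of these. Without gemcitabine replicates 2 and 3 the DNA replication departure was -0.25 and -0.62. The interferon departure was 0.67 without gemcitabine replicate 2 and 0.63 without combination replicate 2, and that of MYC targets -0.18 without combination replicate 3. Limma called 0 genes (849 at an unadjusted p under 0.05, 675 with array weights). The count was 5 and 2 without Group3 tumor replicates 4 and 5, 1 without pemetrexed replicate 1 and 32 without gemcitabine replicate 3. With additive terms the folate and MYC target departures were -0.063 and -0.026.

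No list, and no gene adjusted over all genes, separated pemetrexed from gemcitabine. Gins1, a replication helicase subunit gene, differed by 0.50 (SE 0.18) between them, Espl1, the separase gene, by -0.54 (SE 0.24) and Hba-a1 by -1.38 (SE 0.50). Adjusted over the list alone, 1 red blood cell gene was lower in pemetrexed. Of the 27 lists 0 passed camera, with the smallest adjusted p of 0.173 for DNA replication and granule neuron differentiation, and limma called 0 genes (392 at an unadjusted p under 0.05, 15 with array weights). The count was 3 without pemetrexed replicate 1 and 6 without gemcitabine replicate 3. With 2 and 3 arrays, a p past no threshold does not show that the drugs act alike.

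**Figure D3:**
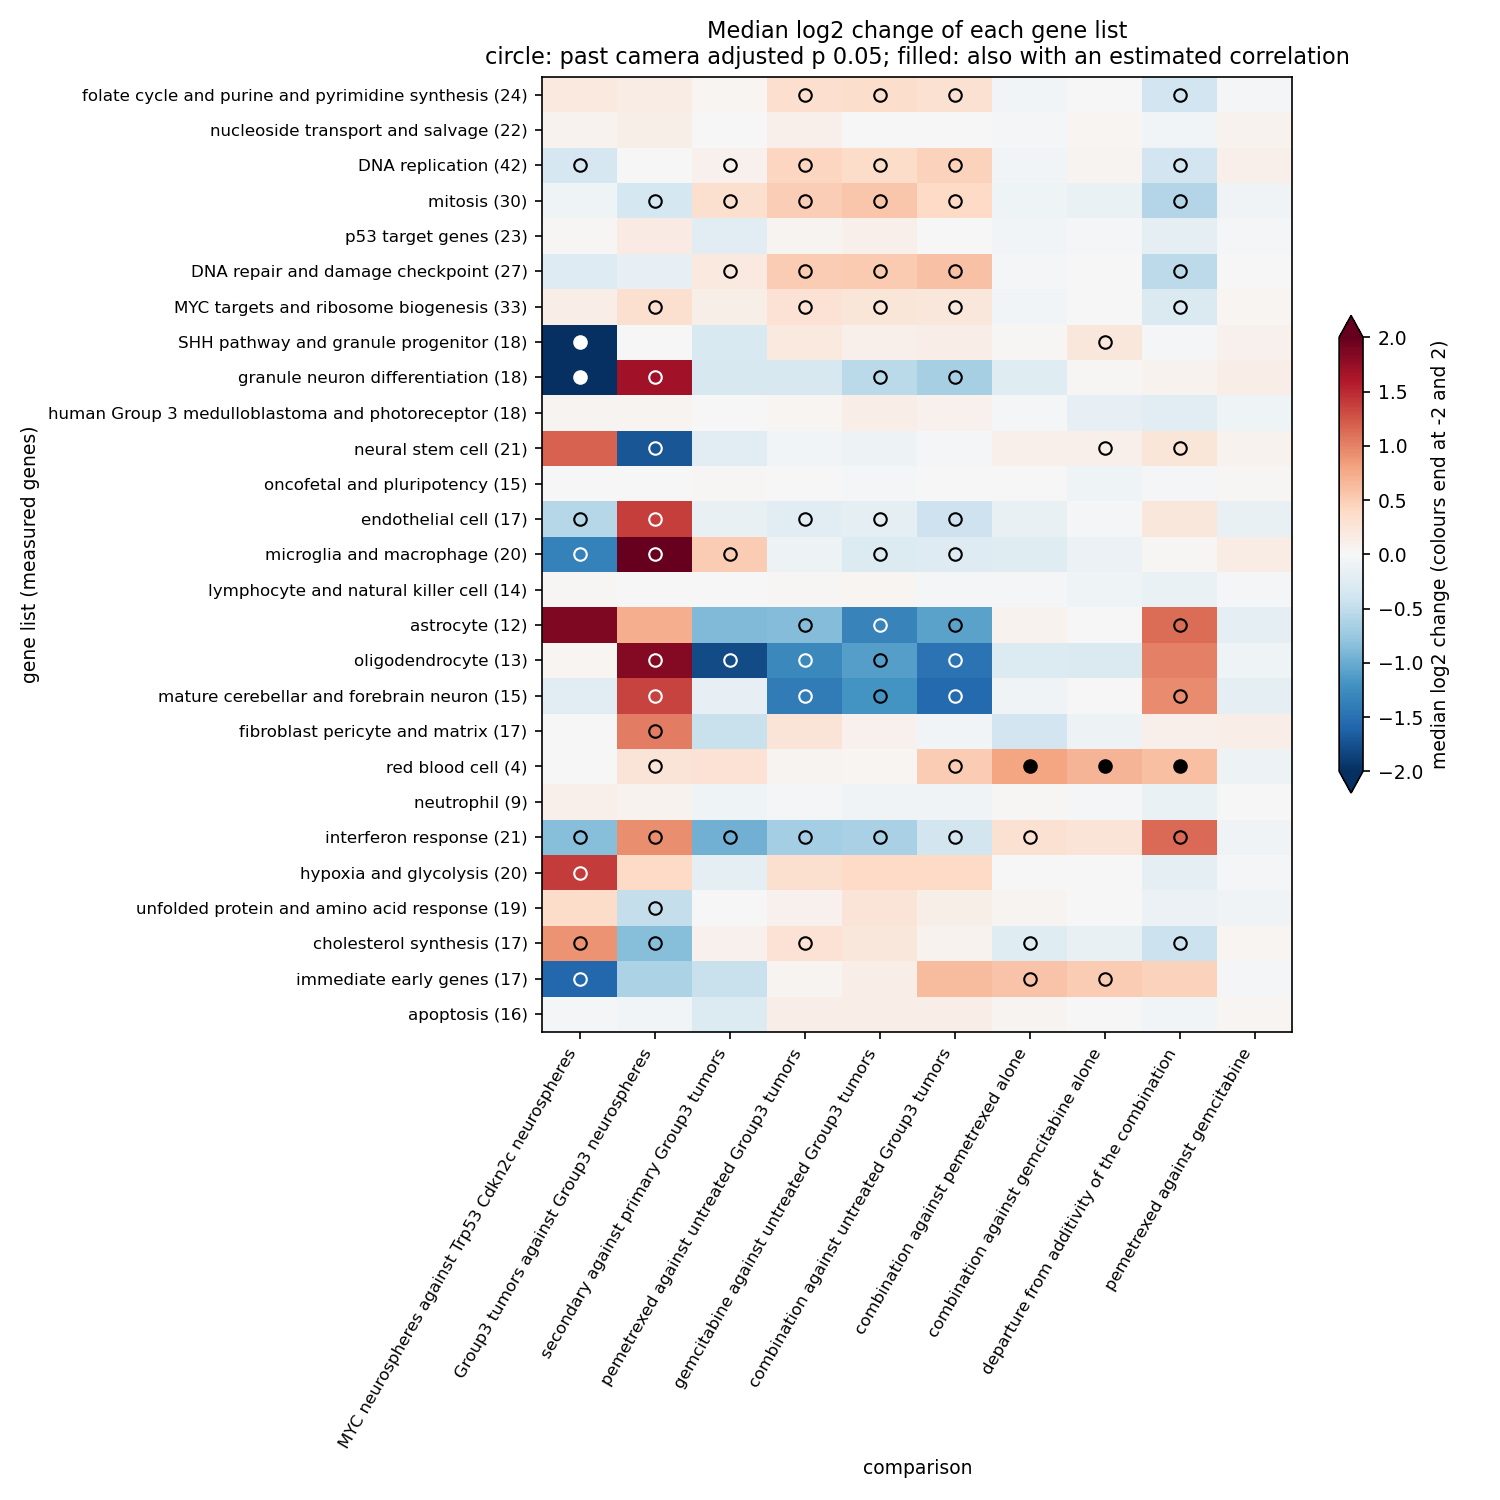
Median log2 change of each of the 27 gene lists (rows) in each of the 10 comparisons (columns), as colour from -2 to 2; an open circle marks a camera adjusted p under 0.05 and a filled circle a call kept with an estimated correlation. Replication, mitosis and repair lists were positive and brain cell lists negative in each drug comparison with untreated tumors.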

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

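Sets of values were screened for arrays lying far from the rest of their group. Only untreated Group3 tumors (5 arrays) and Group3 neurospheres (7 arrays) were screened, with both title codes together. The smaller groups, among them all drug-treated and secondary tumors, were not screened. Of 60 sets of values, 4 held such an array where chance gives 3, about 1 in 20. The tests of the patterns below were chosen after the result was seen, except the counts for other splits of the arrays and the test for RNA shared between codes, which were written before.

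The array lying apart from its group had a nucleoside transport and salvage mean of 8.31 in Group3 tumor replicate 2 (the others 8.02 to 8.09), a neutrophil marker mean of 4.53 in Group3 tumor replicate 1 (3.90 to 4.06), an SHH list mean of 7.90 in Group3 neurosphere replicate 5 (6.98 to 7.30) and a neural stem cell mean of 6.31 in Group3 neurosphere replicate 4 (7.68 to 8.58). A difference between groups of samples was found for 1567 genes and 14 lists whose tumor against neurosphere change differed between title codes, and for 11 lists whose gemcitabine change differed with and without pemetrexed. With an estimated correlation 0 of the 14 lists and 1 of the 11 passed. Data that no comparison used were the probe sets without a gene name: 2792 of 15588 passed in the neurosphere comparison, 2236 in tumors against neurospheres, 395 in secondary tumors (331 higher) and 11 in the combination.

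The Mycn probe sets moved apart in neurospheres of the Myc genotype. A rise of the whole Mycn transcript is argued against by the fall of the others, of which the smaller was -3.81. The bright probe set could read the introduced construct or another transcript: its lowest array of the Myc genotype lay 7.57 above the highest Trp53 Cdkn2c array. That gap cannot separate these from genotype itself, and the probe sequence was not used here.

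Brain cell markers were lower and proliferation lists higher in treated than in untreated mmm tumors. Differing amounts of normal brain tissue in the samples may account for much of this, since 35.3% of the DNA replication difference was left with the brain marker mean as a covariate (51.0% for DNA repair, 38.5% for mitosis). What was left was 0.15 (SE 0.077) for DNA replication and 0.28 (SE 0.091) for DNA repair. A drug effect could do the same, as 7 of 8 treated tumors lay above both untreated mmm tumors in the replication list, and 8 of 8 in the mitosis, repair, MYC target and folate lists. The untreated dka tumors had replication means of 8.96 to 9.31 and mitosis means of 9.27 to 9.48. Every treated tumor lay lower (at most 8.92 and 9.26). In the repair list they overlapped (7.83 to 8.04 against at most 7.88). The codes differ, so whether the untreated mmm tumors were unusual cannot be told. The arrays cannot tell these apart, because less brain tissue could itself follow from treatment or from dissection.

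The neurosphere means of the title codes were nearly equal. An adjustment of the mmm arrays to the dka neurospheres may have been made: the SD of the difference between replicates 1 to 3 and 4 to 6 was 0.132, where the other 9 ways to split them gave 0.292 to 0.410, and 10 splits are too few for a share under 0.05. Replicate 7 lay at an SD of 0.563 from the mean of replicates 1 to 3. The same RNA under both codes could not be told from separate RNA, as the closest pair across codes differed by 0.451 and the closest within a code by 0.452. If an adjustment was made, the mmm and dka tumor changes are not independent of each other.

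Splitting the arrays of a comparison in other ways gave, at most, 0 genes for neurospheres (real 3865), 40 for secondary tumors (real 92) and 138 for the combination against gemcitabine (real 0). In the first pair of these 1 of 10 splits, the real one, had as many genes, and in the last 10 of 10; 10 splits are too few for a share under 0.05. For tumors against neurospheres 1 of 100 splits, the real one, reached 4611 and the highest other gave 2881.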

How the results depend on the processing

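Analysis choices and alternatives were fixed before the data were examined, except those called added. List tests with single arrays left out were also added. No paired analysis was possible because the labels give no replicate numbers that link arrays between groups. The count of 92 for secondary tumors became 1 with only the compared arrays, 199 with additive group and code, 219 with the mean of all probe sets and 593 with array weights. Pemetrexed gave 2 with additive terms and 201 with weights, and gemcitabine 3922 with weights and 2 with only the 10 tumor arrays (added). The combination gave 0 with only the compared arrays, 3 with additive terms, 0 without the 40% dimmest genes, 0 after quantile normalization, 523 with weights, and, added, 3 with the 10 tumor arrays and 0 with the brain marker covariate. Weights gave 8 against pemetrexed (2 with a trended and robust variance), 246 against gemcitabine, 675 for additivity and 15 for pemetrexed against gemcitabine. The 83 list calls became 5 with an estimated correlation, 29 with fry, 50 with additive terms and 56 with the covariate (added), which is made of the neuron, astrocyte and oligodendrocyte markers and takes out their change by construction. Leaving out single arrays gave 2933 to 3346 genes for neurospheres, 3278 to 4851 for tumors against neurospheres, 38 to 215 for secondary tumors, 0 to 10 for pemetrexed, 0 to 324 for gemcitabine, 0 to 33 for the combination, 0 to 5 and 0 to 32 for the combination against pemetrexed and gemcitabine, 0 to 32 for additivity and 0 to 6 for pemetrexed against gemcitabine. Mycn reversed its sign (-0.85, mean of all probe sets). Camera's direction reversed, at the medians given, with additive terms for folate (-0.035, -0.017 and -0.048 for pemetrexed, gemcitabine and combination, -0.063 in additivity), MYC targets (0.0089, -0.027, -0.066 and -0.026) and microglia (0.25 in gemcitabine, 0.17 in combination); without combination replicate 3 for microglia in the combination (0.048, against -0.56 without replicate 2) and without replicate 2 for immediate early genes against pemetrexed (-0.0039, against 0.80 without replicate 3); and with the covariate for interferon in the combination (0.34). The covariate values for astrocytes (0.15, -0.15 and 0.37) and oligodendrocytes (0.20 and 0.30), also reversed, are no test of these lists. The additive fit brings the untreated dka tumors into the control, so its reversals concern a different control. The cause of the remaining reversals was not tested.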

Other observations

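Values under 2.5 were absent from the dka arrays and from Group3 neurosphere replicate 7, while the other mmm arrays held 33 to 112 each. Secondary tumor replicates 2 and 3 correlated at r = 0.993 and replicate 1 with either at 0.961; gemcitabine replicates 1 and 2 correlated at 0.988 and replicates 2 and 3 at 0.929. Xist, the X inactivation transcript, read 12.8 in Trp53 Cdkn2c neurosphere replicate 3 against 6.99 and 5.16 in the others, where the Y-linked Eif2s3y read 9.46 and 8.86 against 3.34. Group3 neurosphere replicates 6 and 7 held both Xist (10.2 and 11.7) and Eif2s3y (10.7 and 8.49). Microglia and macrophage markers averaged 5.76 in Trp53 Cdkn2c neurospheres and 3.99 in dka Group3 neurospheres.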
